A study of Populus x canadensis with 3 samples.

How the data were processed

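Root RNA of the hybrid poplar Populus × euramericana "Neva" was sequenced in 3 groups with 1 library each. Per the labels' protocols, plants grown for 60 days in water culture received para-hydroxybenzoic acid, a phenolic acid abbreviated pHBA, at 0, 2 or 4 mM for 3 days. The RNA samples of a treatment were mixed in equal amounts before sequencing, so a library stands for a pool of plants and there is no replicate error. Libraries were made from total RNA with standard Illumina reagents, per the labels' protocols. Small RNA and degradome libraries of the same work were not analysed here.

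The 2 deposited tables describe the whole series. One holds the predicted coding sequences of a de novo transcript assembly, and the other holds their positions on the assembled contigs. Per the file headers, the contigs came from Trinity and the open reading frames from TransDecoder. The versions, the read filters and the libraries that entered the assembly are not given in the sources used here. The coding score of each open reading frame is a value that the predictor wrote, per the file headers, and it is not a measure of expression. Per the file headers, 14578 open reading frames had a refined start codon. The same number of records were more than 1 codon shorter than the length in their header. Lengths were therefore taken from the sequences. No value per library was used, so sequencing depth per library is unknown and the doses were not compared. The number of unused columns with values per sample was 0.

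Each coding sequence was translated with the standard code. The Trinity gene, a cluster of contigs named by the assembler, was the unit of counting. A locus broken into several clusters is counted more than once, and near-identical copies of a locus can share a cluster. The open reading frame types are those of the headers. A complete frame has a start and a stop codon, a 5′ partial frame lacks the start, a 3′ partial frame lacks the stop, and an internal frame lacks both.

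Before the data were examined, 51 protein families were fixed, each with a short sequence motif written from general knowledge. Motif matches were counted and set against 20 versions of all proteins with shuffled residues. A family was taken as present when its count was above the highest of the shuffles. Members that lack the exact motif, or whose fragment does not reach it, were missed. The share of a family's genes with a complete open reading frame was placed among 10000 random gene lists of the same size, matched in 10 bins on the length of the longest coding sequence. A gene counted as complete when any of its contigs held a complete frame, also one without the motif. The percentile describes this assembly and is not a test. The matched length is the assembled one, so fragments of long proteins are compared with whole frames of short ones. The lists were not matched on contigs per gene, and a gene with more contigs has more chances of a complete frame. Intervals on shares are Wilson intervals at 95% and cover counting error only. A share of 0 is also given with the limit of 3 counts. The text names each family that passed the shuffles, and for a theme it may name the member with the longest complete open reading frame. The exceptions, where a feature was singled out after its values were seen, are stated with the feature.

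Before the data were examined, 25 conserved plant miRNA sequences were also fixed, with a textbook target family for 20 of them. Sites were searched without gaps on the sense strand of coding sequences only, so sites in untranslated regions were not searched. A mismatch cost 1 and a G:U pair 0.5, doubled at miRNA positions 2 to 13, and sites with a total score of 3 or less were kept. The number of genes with a site was compared with 100 shuffles of the same miRNA in a one-sided permutation test, adjusted by Benjamini-Hochberg over the 25 miRNAs. The smallest p these shuffles can give is 0.0099. The overlap of site genes with the textbook family was tested by two-sided Fisher's exact test, adjusted over the 20 miRNAs, and over 3 tests for the relaxed motifs. For each miRNA the text may name the Trinity gene with the lowest score.

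Substitutions were counted between complete coding sequences of equal length from the same Trinity gene that differed at 0.1% to 5% of bases, with 1 pair per gene. The interval over genes used 1000 bootstrap draws. The GC content at the third codon position, called GC3, was taken from the longest coding sequence of each gene, and the limit of 60% was compared with 55% and 65%. After family values had been seen, 12 families of plant regulators and 8 families common to eukaryotes were chosen as classes, 13 further families common to eukaryotes were added to the second class in another setting (histone H4 and polyubiquitin were left out because their motifs are the full plant proteins), and 6 markers of other organisms and of photosynthetic tissue were added. Ubiquitin repeats of 76 residues were sorted by the residues at positions 19, 24, 28 and 57, also after the composition had been seen.

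The searches were tested on simulated data. On 5000 shuffled proteins all 200 implanted copies of each of 4 motifs were found, with 0 others. On 3000 shuffled coding sequences all 200 implanted sites of each of 5 miRNAs were found. For 300 simulated gene pairs, a simulated share of 33.3% at the third codon position was recovered as 35.0% and a share of 70.0% as 68.4%. Other settings were complete frames only, at least 200 residues, distinct sequences, other miRNA score limits and shuffles, and other isoform pairs. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.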

Results

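The series was set up to follow how poplar roots respond to pHBA, a phenolic acid, at 0, 2 and 4 mM. Its root transcriptome was available as an assembly of coding regions that carries no value per library. No gene could therefore be called higher or lower at any dose, and what follows describes the genes assembled from the root RNA. The species of origin of these genes was not determined, and the assembly also held ubiquitin types other than the plant one. The values have no replicates.

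The root assembly held 222005 open reading frames on as many contigs, grouped into 98657 Trinity genes. They encoded 192278 distinct proteins over 170777688 coding bases. Complete frames numbered 80118, or 36.1%, against 62635 without a start codon (28.2%), 23578 without a stop codon (10.6%) and 55674 lacking both (25.1%). The median protein had 195 residues and the longest 2762. Complete frames had a median of 257 residues and internal frames 141. In contigs that carried a complete frame the median 5′ untranslated stretch was 170 bases and the median 3′ stretch 313 bases. The share of complete frames was 14.8% in contigs under 1000 bases and 73.5% in contigs of 2000 bases or more. Most Trinity genes were represented by a single contig (67.2%), and 25432 genes, or 25.8%, had a complete frame. The coding score had a median of 33.0 and lay below 0 for 575 frames.

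Families for the handling of foreign compounds were found in the root assembly, but which of their genes come from poplar was not determined. Cytochromes P450, monooxygenases that oxidise small molecules, were found in 250 Trinity genes, against at most 24 in shuffled proteins. ABC transporters, which export conjugates and other solutes, were found in 267 genes, but their loose motif also matched up to 83 genes by chance. UDP-glycosyltransferases, which attach sugars to phenolics and other acceptors, numbered 63 genes. Tau-class glutathione S-transferases, which join glutathione to reactive compounds, numbered 12 genes. No shuffle matched either of these last families. Complete frames were present for 65.1% of the glycosyltransferase genes and for 9 of the 12 glutathione S-transferase genes, at the 98.8th and 100th percentile of length-matched lists. A complete frame that itself carried the motif was found in 34 of the 63 and 8 of the 12 genes. The share was 44.8% for cytochromes P450 (21.4th percentile) and 37.1% for ABC transporters (1.54th percentile), but both families lay at the 100th percentile without length matching. The longest complete frame of the theme was an ABC transporter of 1715 residues on TRINITY_DN184858_c0_g3_i6, at bases 955 to 6102 of the minus strand.

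Antioxidant enzymes formed the next theme. Plant secretory peroxidases, which use hydrogen peroxide to oxidise phenolics, were found in 73 genes against at most 21 by chance, and 58.9% of them had a complete frame. Iron or manganese superoxide dismutases numbered 31 genes and copper/zinc superoxide dismutases 10. Catalase, which breaks down hydrogen peroxide, was found in 12 genes, the disulphide oxidoreductase group of glutathione reductase in 27 and ascorbate peroxidase in 2. The copper/zinc motif matched up to 5 genes by chance. With proteins of at least 200 residues it matched 4 genes, against at most 5 by chance, so that family then no longer stood above the shuffles.

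The 4 families grouped under the phenylpropanoid pathway, which makes lignin and phenolic acids, held 49 genes, 37 of them multicopper oxidases. Phenylalanine ammonia-lyase, the entry enzyme, was found in 3 genes, the 4-coumarate-CoA ligase box in 7 and the chalcone synthase group in 2. The longest complete frame of the theme encoded a phenylalanine ammonia-lyase of 715 residues on TRINITY_DN190403_c0_g1_i4. Of the multicopper oxidase genes, 37.8% had a complete frame. Laccases belong to this family and were not told apart from its other members, so the 49 genes are not a count of pathway enzymes.

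Among transcription factors, the motif of WRKY proteins, known for roles in defence and stress, matched the most genes, with 76. R2R3-MYB proteins followed with 42 genes, bHLH with 29, NAC with 22, ERF with 20, and SBP and HSF with 17 each. MADS proteins numbered 16 genes, ARF and AP2 proteins with a double domain 13 each, GRAS 8, HD-ZIP III 7, NF-YA 6, GRF 5 and TCP 4. These counts depend on the motif, since relaxed motifs chosen after the values were seen matched 21 ARF and 19 GRAS genes. The order of the families need not be one of family size. No shuffle matched any of these 15 families. Complete frames were found in 67.1% of the WRKY genes (Wilson interval 55.9% to 76.6%) and in 93.8% of the MADS genes (71.7% to 98.9%). Both shares lay at the 100th percentile of length-matched lists, which were not matched on contigs per gene. The 76 WRKY genes held 345 frames with the motif and the 16 MADS genes 85, while all genes had a mean of 2.25 contigs. No HD-ZIP III gene of the 7 had a complete frame, which allows a share of up to 42.9% by a limit of 3 counts (Wilson upper bound 35.4%). The longest complete frame among transcription factors was a bHLH protein of 873 residues on TRINITY_DN188885_c0_g1_i9.

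Immune receptors with an NB-ARC domain, the nucleotide-binding part of resistance proteins, were found in 48 genes, and thaumatin-like and family 19 chitinase proteins in 14 and 9. Of the NB-ARC genes, 27.1% had a complete frame (Wilson interval 16.6% to 41.0%), close to the 25.8% of all genes. This share lay at the 0.21th percentile of length-matched lists, but at the 59.4th without length matching. Aux/IAA repressors of auxin signalling numbered 20 genes and Argonaute proteins, which bind small RNAs, 11. ATP sulfurylase, which activates sulfate, was found in 3 genes. The motif of serine/threonine kinases matched the most genes of any family, with 1157. P-type ATPases numbered 104 genes and aquaporins 40, the aquaporin motif matching up to 19 by chance. Copia and gypsy reverse transcriptases were found in 4 and 3 genes, the copia motif matching up to 3 by chance.

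**Figure D1:**
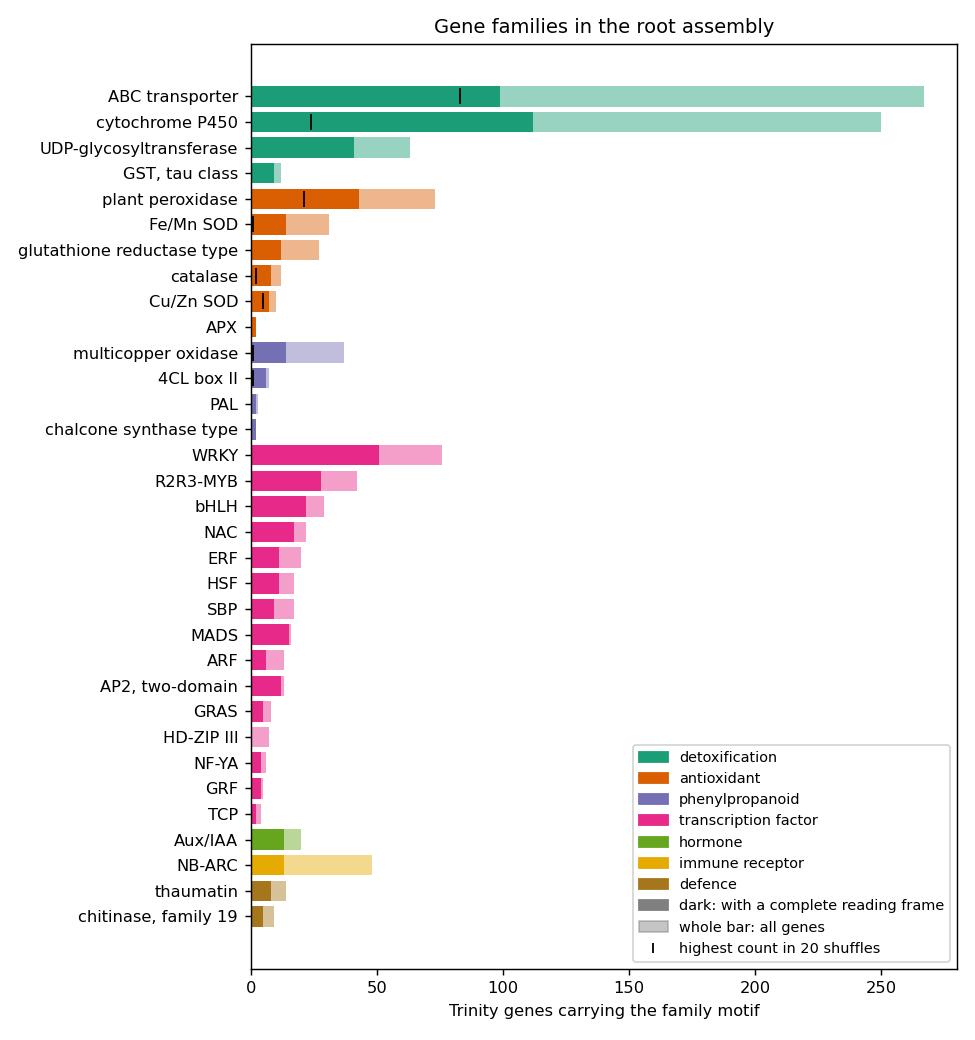
Trinity genes that carry each family's motif, by theme. Each whole bar is the gene count, and each black mark is the highest count in 20 sets of shuffled proteins. The dark part of a bar shows genes with a complete open reading frame on any contig, which need not carry the motif. Of the families plotted, the motifs of ABC transporters (267 genes) and cytochromes P450 (250 genes) matched the most genes. Among transcription factors the WRKY motif did, with 76 genes. Motifs differ in how many members they catch, so the order need not be one of family size.

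Housekeeping and chaperone families differed in how often they had a complete frame. The signature of translation factor GTPases, the family of EF1A, was found in 99 genes, tubulin in 93, HSP70 in 61, actin in 32, HSP90 in 31, the plant polyubiquitin motif in 17 and the full plant histone H4 protein in 7. No actin gene of the 32 had a complete frame, which allows a share of up to 9.38% by a limit of 3 counts (Wilson upper bound 10.7%). Complete frames were found in 18.0% of the HSP70 genes (Wilson interval 10.4% to 29.5%) and 18.3% of the tubulin genes (11.7% to 27.3%). The length-matched medians were 41.0% and 34.4%. HSP90 and polyubiquitin lay within the middle 95% of length-matched lists. Of 50 families above chance, 17 lay above and 7 below the middle 95% of length-matched lists for completeness. The 7 were actin, tubulin, EF1A, HSP70, P-type ATPases, ABC transporters and NB-ARC. Without length matching actin alone of the 7 stayed low, 4 lay in the middle 95%, and ABC transporters and P-type ATPases moved to the 100th and 99.7th percentile, so the other low calls depend on the matching. The 17 high families stayed high; histone H4 is among them, but its motif is the full protein, so its fragments could not be counted.

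Markers of other organisms were mixed. The chitin synthase motif of fungi and arthropods was found in 15 genes against at most 7 by chance, and a bacterial chemotaxis receptor motif in 1 gene. A histidine kinase motif of the bacterial type was also found in 1 gene, which was no more than by chance, the only family of the 51 that did not pass. The sigma-54 interaction motif was found in 80 genes, but it also fits small GTPases and so does not by itself point to bacteria. Which of the 80 genes encode GTPases was not tested.

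The series pairs this transcriptome with small RNA libraries, which raises the question of which root transcripts could be bound by conserved miRNAs. Coding sequences with a site were more numerous than for shuffled miRNAs in 10 of 25 cases. miR156, miR160 and miR172 each had sites in 8 genes, miR166 and miR397 in 6, miR159 and miR171 in 5, miR164 in 3, and miR393 and miR828 in 2. Adjusted p from the one-sided permutation test was 0.0309 for 8 of these miRNAs and 0.0495 for miR164 and miR393. 7 miRNAs, namely miR162, miR167, miR319, miR398, miR399, miR403 and miR408, had sites in 0 genes. At a score limit of 4, miR319 had sites in 12 genes and passed (adjusted p = 0.0354 in the permutation test), 2 of them TCP genes, and miR408 had sites in 6 and did not. At the main limit the other 8 had sites in 1 or 2 genes and did not pass.

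The genes with sites belonged to textbook target families for 9 of 20 miRNAs. Several site genes, as for miR156 and miR171, have names that differ in the last number alone and may be pieces of the same locus. The p-values treat Trinity genes as independent, so they overstate the evidence where a locus was split. For miR156, 6 of 8 site genes were SBP factors (adjusted p = 5.41e-21, Fisher's exact test). For miR397, 5 of 6 were multicopper oxidases (adjusted p = 3.36e-16, Fisher's exact test). For miR166, 3 of 6 were HD-ZIP III factors, and for miR172, 3 of 8 were AP2 factors with a double domain (adjusted p = 2.92e-11 and 5.00e-10, Fisher's exact test). Both site genes of miR828 were R2R3-MYB factors (adjusted p = 7.08e-07, Fisher's exact test). miR164 reached 1 NAC gene among 3, miR395 1 ATP sulfurylase among 2, miR858 1 R2R3-MYB among 2 and miR472 1 NB-ARC gene, its only site gene. The sites of miR472 and miR858 overlapped the bases that encode the family motif itself, so those overlaps are not independent of the search. No site gene of miR159, miR160 or miR171 carried its family's motif. With relaxed motifs chosen after these values were seen, and adjustment over these 3 tests alone, 4 of 8 site genes of miR160 were ARF factors (adjusted p = 3.18e-13, Fisher's exact test) and 2 of 5 of miR171 were GRAS factors (adjusted p = 5.27e-07, Fisher's exact test). The third test, of miR167 with ARF, had 0 site genes.

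Individual sites varied in closeness, and several miRNAs had tied best sites. For miR171 all 5 site genes had a score of 0; the longest of them, TRINITY_DN191762_c4_g1, held GATATTGGCGCGGCTCAATCA at coding bases 1092 to 1112, complementary to UGAUUGAGCCGCGCCAAUAUC without a mismatch. The best miR156 site, GTGCTCGCTCTCTTCTGTCA, lay at coding bases 890 to 909 of the SBP gene TRINITY_DN184292_c0_g1 with a score of 0.5. For miR160, 4 genes tied at 0.5, and the longest, TRINITY_DN187199_c1_g2, held TGGCATGCAGGGAGCCAGGCA at coding bases 1311 to 1331. For miR397, 2 multicopper oxidase genes tied at 1.5, and the longer, TRINITY_DN185463_c0_g3, held GATCAATGCTGCACTCAATGA at coding bases 447 to 467. The best miR395 site scored 1.5 in the ATP sulfurylase gene TRINITY_DN188968_c2_g1. Both R2R3-MYB genes of miR828 scored 2, the longer being TRINITY_DN180278_c1_g3. Of the 2 miR172 genes tied at 2, the longer, TRINITY_DN189629_c0_g1, was an AP2 gene and the other lacked the family motif. The best miR169 site scored 1 in TRINITY_DN182884_c1_g1, the best miR164 site 2 in TRINITY_DN184163_c0_g3 and the best miR166 site 2 in TRINITY_DN179351_c0_g5. These genes did not match the motif of the textbook family. Their sites lie on partial frames, and whether those frames cover the region of the motif was not tested. The best miR394 and miR393 sites, for which no family was tested, scored 1 in TRINITY_DN188550_c0_g2 and 2 in TRINITY_DN190266_c2_g1. The best sites of the other 6 miRNAs with a site scored 2.5 or 3.

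With shuffles that keep dinucleotides 6 of the 10 miRNAs passed, and miR156, miR164, miR393 and miR828 did not (adjusted p = 0.0675, 0.0675, 0.0675 and 0.0619 in the permutation test). Of the 10, miR160 and miR172 alone passed under every other setting run, and at a score limit of 2 the family overlaps of miR164, miR166, miR472 and miR858 no longer passed.

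**Figure D2:**
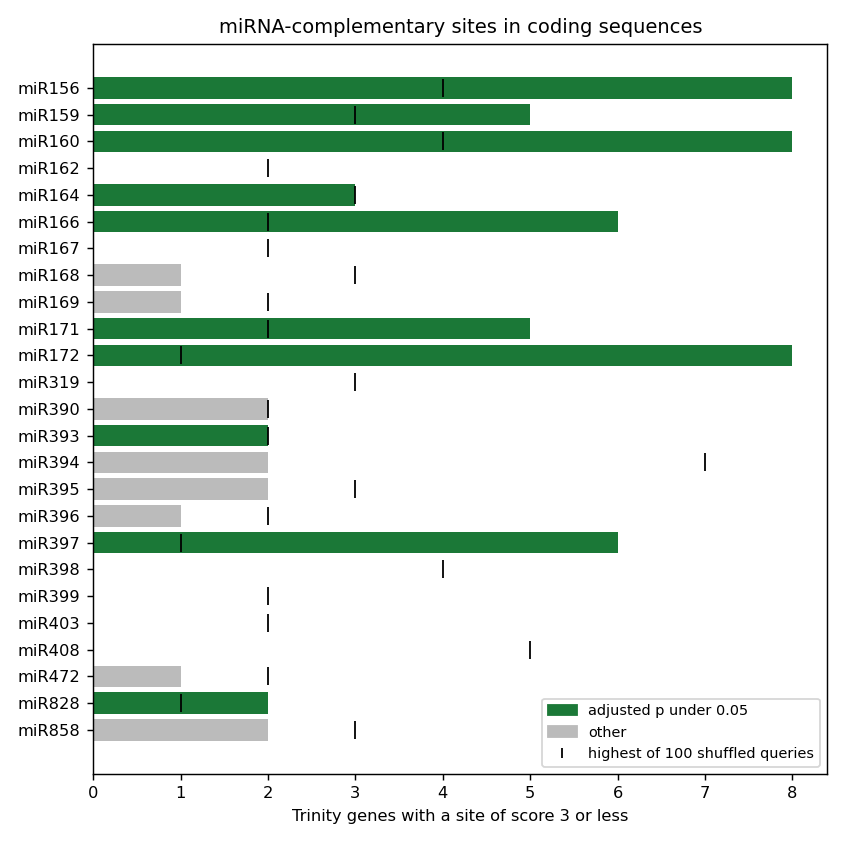
Trinity genes with a coding site of score 3 or less for each of 25 conserved miRNAs; green bars have an adjusted permutation p under 0.05, grey bars do not, and each black mark is the highest count among 100 shuffled versions of that miRNA. miR156, miR160 and miR172 each reached 8 genes.

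Copies of the same Trinity gene differed mostly at silent positions, a question raised by the hybrid origin of the clone. Between complete coding sequences of equal length in 3822 genes, 50301 substitutions were counted. Of these, 21.7% fell on the first codon position, 16.2% on the second and 62.1% on the third (Wilson interval 61.7% to 62.5%, and 61.4% to 62.8% by bootstrap over genes). Of the codons with a single substitution, 64.7% kept the residue, and transitions made up 62.9% of the substitutions. The median pair differed at 0.741% of bases. The third-position share was 73.0% in genes with a GC3 above 60% (69.2% to 76.6% by bootstrap over genes) and 61.5% in the others (60.8% to 62.2%).

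Base composition differed between plant regulators and some families of general cell machinery. GC3 was above 60% in 10 of 247 genes of 12 plant regulator families, among them WRKY, NAC and R2R3-MYB, or 4.05% (Wilson interval 2.21% to 7.29%). It was above 60% in 224 of 478 genes of 8 families found across eukaryotes, among them actin, tubulin and HSP70, or 46.9% (42.4% to 51.3%). The difference was 42.8 percentage points (interval 37.3 to 47.7). By family, the share above 60% was 5.26% for WRKY, 59.0% for HSP70, 64.5% for HSP90, 53.8% for tubulin, 31.7% for P-type ATPases and 28.1% for actin. Several other families found across eukaryotes lay below the 31.3% of all genes, with 20.7% for serine/threonine kinases, 25.0% for catalase, 20.0% for copper/zinc superoxide dismutase and 5.88% for HSF. Iron or manganese superoxide dismutase (51.6%) and the glutathione reductase group (48.1%), both among the 8 families, lay above it. ABC transporters, which are outside the 8, had 32.6%. With 13 such families added, 26.5% of 2326 genes were above 60% (24.8% to 28.4%), and the difference from the plant regulators was 22.5 percentage points (18.8 to 25.1). In the 13 families without the first 8 the share was 21.3% (19.5% to 23.2%), a difference of 17.2 percentage points (13.5 to 19.9). A complete frame was present in 17.7% of the genes above 60% and in 29.5% of the rest, and a single contig made up 76.0% and 63.2% of them. All these classes were chosen after family values had been seen, so no test of the difference is given.

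**Figure D3:**
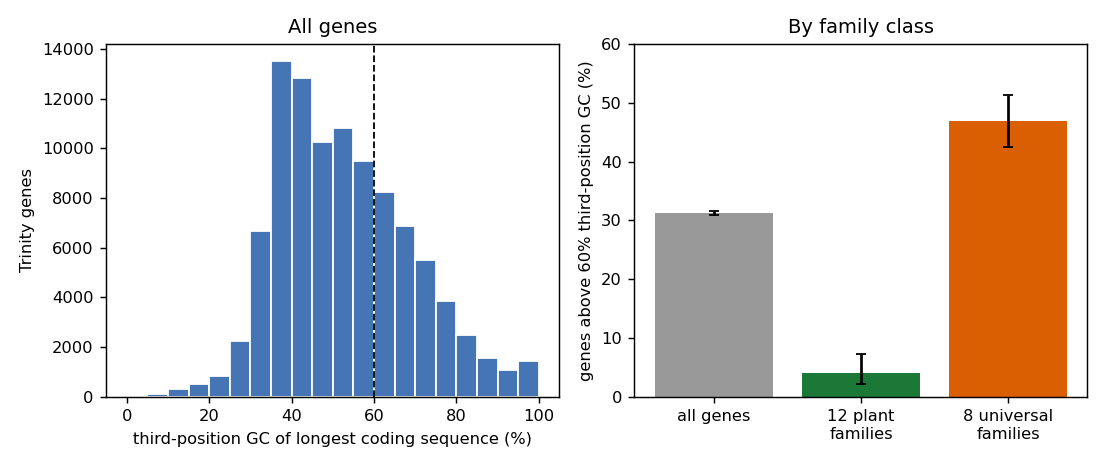
Left, Trinity genes by the GC content at the third codon position of their longest coding sequence, with a dashed line at 60%; right, the share of genes above 60% in all genes, in 12 plant regulator families and in 8 of the families common to eukaryotes, with Wilson 95% intervals. The shares were 31.3%, 4.05% and 46.9%.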

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

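All tests in this part apart from the length test of the GC3 difference were chosen after the composition of the assembly had been seen. The length test was chosen before its result, but it uses family classes chosen after family values had been seen.

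Ubiquitin, a protein of 76 residues with almost no variation within a lineage, was outside the planned families except for its plant form. It stood out because 45 Trinity genes carried a full ubiquitin repeat other than the plant protein, above the limit of 3 that a count of 0 allows. In all, 59 genes carried 11 protein types, and 17 genes carried the plant type, 3 of them beside another type. The yeast type was found in 13 genes, the animal type in 6, and a type with glutamine at position 28 and otherwise the plant residues in 16. GC3 had a median of 68.6% for the yeast type, 71.0% for the animal type and 32.8% for the glutamine type.

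The difference in GC3 between families common to eukaryotes and plant regulators was weighed against 3 explanations. Short fragments with noisy composition were argued against, because with at least 200 residues the difference was still 40.7 percentage points (interval 34.0 to 46.6). With 13 further families in the common class the difference was 22.5 points, and 17.2 points with these families alone. Transcripts of other eukaryotes in the root RNA may add to the difference, as a hypothesis, since 45 genes carried another ubiquitin. Of these, 42.2% were above 60%, against 4.05% in plant regulator families. Also above 60% were 8 of 15 chitin synthase genes, but that motif matched up to 7 genes by chance. The same held for 3 of 4 genes with the cellulose-binding motif of fungi and oomycetes. Against this, the glutamine type had 0 of 16 genes above 60%. The animal histone H4 and dynein motifs were found in 0 genes, while the animal ubiquitin type was found in 6. These 0 counts cannot decide, because neither motif was tested on implanted copies. A single poplar proteome predicted 0 genes of another ubiquitin, and 45 were found. That prediction was written after the composition had been seen, so the count cannot decide whether poplar is the whole source of the difference. GC-rich housekeeping genes of poplar stay open, because 58.8% of the plant-type ubiquitin genes were also above 60%. The share was 40.5% in the genes without that type (p = 0.254, Fisher's exact test). The species of the plant-type genes was not determined, and no explanation by pHBA dose was tested.

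The helix motif of light-harvesting proteins, which serve photosynthesis, was found in 37 genes although the RNA came from roots. Of these genes, 22 had a GC3 above 60% (59.5%, Wilson interval 43.5% to 73.7%). Whether they come from poplar or from another organism was not determined.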

How the results depend on the processing

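The relaxed ARF and GRAS motifs, the GC3 limits of 55% and 65% and the wider common class were chosen after seeing the data, and the reference match was not run because no poplar genome was used here. The count of 222005 open reading frames fell to 80118 with complete frames only, 108178 with at least 200 residues and 98657 with the longest per gene, by construction. The complete share of 36.1% became 47.5% with at least 200 residues, 19.4% with the longest per gene and 31.2% with distinct sequences, and the median with at least 200 residues was 325. Families above chance numbered 46 to 50 under every setting run; 7 single family calls were lost and 197 did not change. Families with unusual completeness numbered 24, and 31 without length matching, where ABC transporters and P-type ATPases turned from low to high (100th and 99.7th percentile), 4 other low calls were lost and 11 high calls gained. The 10 miRNAs with excess sites fell to 6 with dinucleotide shuffles and 6 with complete frames only, of which 6 and 5 were among the 10 and where the smallest adjusted p was 0.0413; score limits of 2 and 4 gave 10 and 11, of which 8 and 7 were shared. Over single miRNAs 14 calls were lost and 7 gained. Target families fell from 9 to 5 at a score limit of 2, and numbered 11 at a limit of 4 and with relaxed motifs. The share of substitutions at the third codon position was 60.3% for pairs differing at up to 2% and 61.7% for the closest pairs. Genes above the GC3 limit made up 21.4% with complete frames, 27.9% with at least 200 residues, 41.0% at 55% and 23.1% at 65%, while the difference between family classes, 42.8 percentage points, became 31.4 with complete frames, 40.7 with at least 200 residues, 49.4 at 55%, 36.7 at 65% and 22.5 with the wider common class. Apart from the construction of the sets, the cause was not tested. Depth per library is unknown and limits which transcripts were assembled.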

Other observations

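The markers in this paragraph were chosen after the composition had been seen, and the tests of the later paragraphs before their results. The cellulose-binding motif of fungi and oomycetes was found in 4 genes, 3 of them with a GC3 above 60%. The animal form of histone H4 and the dynein motor motif, which flowering plants lack, were each found in 0 genes.

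Substitutions between copies of the same Trinity gene were weighed against 2 explanations. Sequencing or assembly error spreads over the codon positions alike, and the share of 62.1% at the third position, with a lower bootstrap bound of 61.4%, argues against it as the main source. Diverged coding copies may be the source, as a hypothesis, since 64.7% of codons with a single substitution kept the residue. Alleles of the hybrid and paralogs joined in a Trinity gene were not separated.

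Of the housekeeping and chaperone families, 5 (actin, tubulin, EF1A, HSP70 and HSP90) were pooled, 4 of which had low completeness for their length; polyubiquitin, within the middle 95% of length-matched lists, was not in the pool, nor was histone H4, whose full-protein motif cannot match a fragment. In the pool 21.5% of 316 genes had a complete frame, against a median of 37.0% in length-matched lists and 25.8% of all genes. Fragments of thinly covered transcripts with a high GC3 could contribute, with 14.8% complete above 60% against 35.2% in the lists. The 154 members at or below 60% had 28.6% against 39.0% and still lay at the 0.1th percentile. This cannot decide whether such fragments are the whole source, because the lists were matched on the assembled length, which breaks shorten. Without matching, all genes at or below 60% had 29.5%, close to the share of the 154 members. Near-identical copies that break an assembly were not tested.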
